A study of Arabidopsis thaliana with 4 samples.

How the data were processed

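Total RNA of Arabidopsis thaliana was profiled on 4 arrays, 2 of plants titled control and 2 of plants titled albino. Per the labels, both kinds of plant were segregants of 1 parental line, grown together on plates of diluted Murashige and Skoog medium with 2% sucrose for 3 weeks at 23 °C under 16 h of light and 8 h of dark. Per the labels' protocols, RNA was extracted with TRIzol and cleaned on a column, cDNA was made from 16 µg of total RNA, biotin-labelled cRNA was transcribed from it, and 30 µg of cRNA was hybridized. How the cDNA was primed is not given in the sources used here.

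The deposited values are log2 probe-set summaries, and RMA is the method named per the submitters' processing notes. Its software and version are not given in the sources used here. RMA corrects background within an array, makes the value distributions of the arrays processed together alike, and summarises the probes of each set on the log2 scale, so the values carry no detection call and dim probe sets have compressed differences. The log2 scale was checked on the deposited values, whose medians were 5.842 and 5.846 in control and albino replicate 1 and 6.119 and 6.124 in control and albino replicate 2. The quantiles of the 2 arrays with the same replicate number differed by at most 0.07 (number 1) and 0.085 (number 2), while arrays of different number differed by up to 0.355. The values thus look normalized as 2 separate pairs of arrays, and the counts, the lists with a call and the genes given in most detail are also given with the replicate number as a block and within each pair. The labels do not say that a number marks a shared plate, day or plant pool, nor whether the replicates were separate pools of plants, so p-values measure only the spread between these arrays, which may be technical.

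Groups were taken from the sample titles. The free-text descriptions call all 4 samples wild type, which conflicts with the titles of the albino samples. The labels name no disrupted gene, so no targeted transcript could be used to check the titles, and groups are called "labelled albino" and "labelled control" below.

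The table held 22746 probe sets and 0 Affymetrix control probe sets, so the planned comparison of 3 prime and 5 prime control probe sets was not run. The platform annotation gave 1 gene for 13513 probe sets (13356 distinct genes), several genes for 503 and none for 8730, which are unnamed here. Of the probe sets with 1 gene, 13436 matched a current gene record of the TAIR10.1 assembly, used only for names and for which genes neighbour each other. A gene was represented by its single-gene probe set with the highest mean over the 4 arrays.

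Differences (labelled albino minus labelled control) were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, default prior) over all 22746 probe sets, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 2 residual degrees of freedom, and 1 with the replicate block. Before the data were examined, 30 gene lists with 479 members were written. Of these members 110 were measured here, in 25 lists, and the 11 lists with at least 4 measured genes were tested with camera at a preset inter-gene correlation of 0.01, and with an estimated correlation and fry beside it. Adjustment was over the 11 lists. With an estimated correlation, camera rests on the few residual degrees of freedom of the fit, so a list that fails it is not shown to be unchanged. Standard errors (SE) of a gene's difference are those of the moderated fit without the block, and SDs are over the 2 arrays of a group. Both thus include differences between the replicate numbers. An SE can therefore be larger than with the block, as for the plastid gene rbcL (0.42 against 0.15). SEs of medians and ratios over sets of genes, in the closing observations, are over genes or probe sets of the same arrays. Such genes are not independent replicates, so these SEs do not measure error between arrays. The number of arrays limits the precision.

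The rule for named genes, also fixed before the data were examined, took up to 8 genes per direction among called genes whose groups did not overlap, the 2 members with the smallest p of each list called by camera, the 1 member with the smallest p of every other list with a measured member, and GLK1, GLK2 and HSP21. Its first part named 0 genes, since 0 were called. GLK1, GLK2 and HSP21 are not analysed here, because no single-gene probe set was paired with them. Other genes named below are members of the fixed lists or were chosen after their values were seen, as is said where they appear.

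The alternatives were quantile normalization of all 4 arrays again, centring on the brighter 50% of probe sets, cyclic loess, leaving out the dimmest 25% or 50% of probe sets, a trended and robust prior, no moderation, leaving out probe sets with cross-hybridization suffixes, the replicate block, each array left out in turn, the mean of a gene's probe sets, other thresholds, and other set tests. In the fits without 1 array, the lone array of a group was assumed to vary like the other group. The fit was tested on simulated arrays in 5 runs of 22746 probe sets with 200 changed in each. These arrays had the probe sets' own means and replicate-number differences, the latter equal in both groups, and spreads drawn from the prior of the fit with the block. Without a block it recovered 0 of 500 changes of 1 and 0 of 500 changes of 3 on the log2 scale. With the block it recovered 0.6% of the former and 91.6% of the latter, with 36 false calls over the 5 runs against 0 without it. Of unchanged probe sets, 0.92% without and 5.19% with the block had an unadjusted p under 0.05. The fit without the block was thus conservative in this simulation, which is built as the fit with the block assumes.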

Results

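Transcript levels were measured in 3-week-old Arabidopsis plants of an albino mutant line, with segregants of normal appearance from the same parent as controls. The design asks how a strong albino mutation alters expression across the genome. Each group held 2 arrays, and each array gave log2 RMA values for 22746 probe sets. Over all probe sets, Pearson's r between arrays was 0.962 and 0.988 within the pairs of replicate number 1 and 2, 0.968 between the labelled control arrays and 0.970 between the labelled albino arrays. These correlations are across genes, which are not independent replicates.

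The arrays labelled albino had higher values for many chloroplast-encoded photosynthesis transcripts than the arrays labelled control. The largest of these differences were those of psaA of photosystem I (2.43) and the cytochrome b6f subunit petB (2.31). Of 4 measured markers of oxidative stress and mitochondrial dysfunction 3 were lower in both pairs of arrays. The shifts of the plastid photosynthesis list and of this list were past the threshold only with camera's preset correlation (adjusted p = 0.829 and 0.823 with an estimated correlation). The estimated correlations were 0.385 and -0.286. That test rests on 2 residual degrees of freedom, so failing it does not show that a list was unchanged. Of 12 measured nuclear photosynthesis genes, 4 of them of the Calvin cycle, 8 were higher and 2 lower in both pairs of arrays. These 12 are a minority of the genes listed. Their differences ran from -0.62 for the Calvin cycle gene PGK2 to 1.35 for the antenna gene LHCB4.2 (SE 0.28). The clock gene GI and the thionin gene THI2.1 were higher by 2.04 (SE 0.27) and 2.15 (SE 0.41). No single probe set passed limma's test over the whole array, so the values of single genes below are differences with their errors, not calls. Of the 27 genes named by the rule fixed beforehand, 24 had the same sign in both pairs and 3 (UGT75C1, COR15A and CLV3) did not. The rule takes members with the smallest p on these same arrays, which favours pairs that agree, so this count is no evidence of replication. With the replicate block, the limma adjusted p of the 27 lay between 0.217 and 0.839.

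With limma, 0 probe sets were called higher and 0 lower at an adjusted p under 0.05, and the smallest adjusted p was 0.59. At an unadjusted p under 0.05, which unchanged probe sets reach at a nominal rate of 0.05, there were 609 higher and 701 lower of the 22746. With the replicate number as a block the counts were again 0 and 0 (smallest adjusted p 0.217), with 1631 higher and 1712 lower at an unadjusted p under 0.05. Without albino replicate 2, 30 were called higher and 152 lower, a fit in which the group labelled albino is a single array. An ordinary linear model with no variance moderation called 0 higher and 1 lower.

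The direction of large differences recurred between the pairs of arrays. Of the 22746 probe sets, 185 were at least 2-fold higher and 219 at least 2-fold lower in the labelled albino array of both pairs, and 0 went opposite ways, where independent pairs would give 20.7 in the same and 20.3 in opposite directions. This criterion was added after the data were seen and is no test of single genes. Across probe sets the differences of the pairs, which share no array, had a Pearson's r of 0.593 and a Spearman's rho of 0.43. Differences were wider in pair 1 (SD 0.598) than in pair 2 (SD 0.364).

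**Figure D1:**
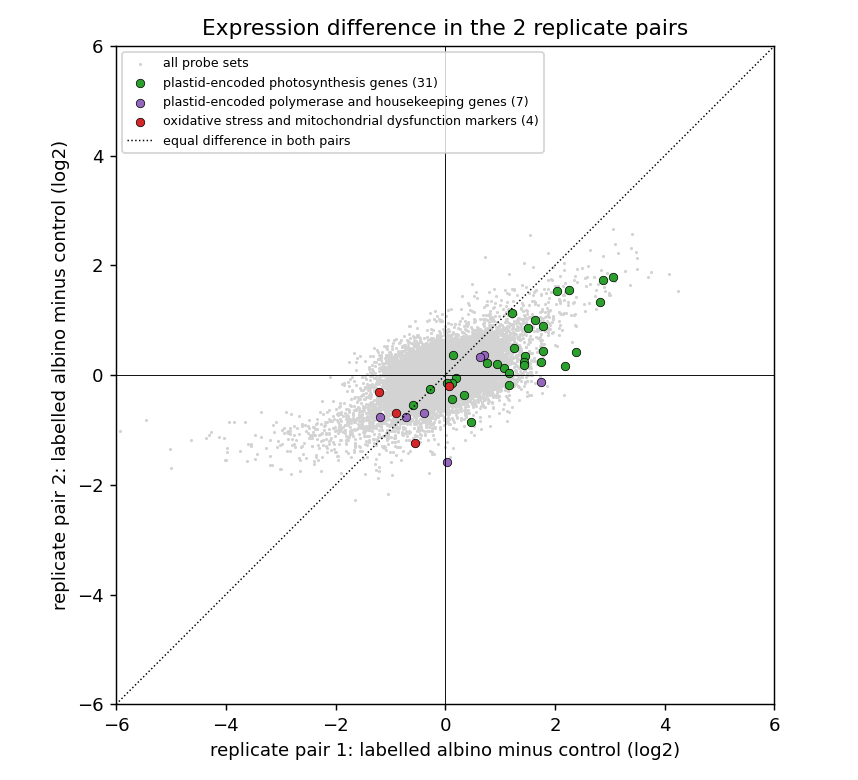
Difference between the arrays labelled albino and control (log2) in replicate pair 1 (x axis) and pair 2 (y axis) for each of 22746 probe sets (grey points), with 3 gene lists in colour and the line of equal difference dotted. Of the 31 plastid-encoded photosynthesis genes, 22 lie above 0 on both axes.

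The plastid-encoded photosynthesis genes, which code for subunits of the photosystems, the cytochrome b6f complex, the ATP synthase and Rubisco, were all measured. As a list of 31 they rose in the arrays labelled albino (median difference 0.83, camera adjusted p = 1.94e-11). The call held with the replicate block (adjusted p = 1.56e-06) but not with an estimated correlation (adjusted p = 0.829) or with fry (adjusted p = 0.523). The median was 1.26 in pair 1 and 0.23 in pair 2, and 22 members were higher and 2 lower in both pairs. Of the 31, 0 passed over all probe sets and 6 passed adjusted over the list alone (9 with the block). These 6 were petB, psaA, psbH, psbZ, psaB and psbK. On the same arrays the abundant root marker PYK10 differed by -1.48 (SE 0.47), with -2.29 in pair 1 and -0.67 in pair 2, and did not pass the test. The other measured root markers, EXPA7 and EXPA18, were dim and differed by -0.28 (SE 0.35) and 0.22 (SE 0.27).

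The value of petB, a core subunit of the cytochrome b6f complex, was 9.56 ± 0.46 (SD, n = 2) in the labelled control and 11.87 ± 0.33 (SD, n = 2) in the labelled albino arrays. The difference of 2.31 (SE 0.34) was 2.87 in pair 1 and 1.74 in pair 2. For psaA, a reaction-centre protein of photosystem I, the values were 8.24 ± 0.64 and 10.67 ± 0.26 (SD, n = 2 each), a difference of 2.43 (SE 0.38) that was 3.06 in pair 1 and 1.79 in pair 2. Both had limma adjusted p = 0.59 over all probe sets and 0.217 with the block. Its partner psaB was higher by 2.08 (SE 0.40), and the photosystem II genes psbH, psbZ and psbK by 1.90 (SE 0.30), 1.78 (SE 0.33) and 1.18 (SE 0.25). Not every member went this way. The large Rubisco subunit gene rbcL differed by -0.56 (SE 0.42) and psbA, coding for the D1 protein of photosystem II, by -0.27 (SE 0.25), each lower in both pairs. Some members hardly moved and had opposite signs in the pairs. Among them were petD of the cytochrome b6f complex (-0.01, SE 0.30) and the photosystem II genes psbB (-0.01, SE 0.26) and psbT (-0.06, SE 0.26).

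**Figure D2:**
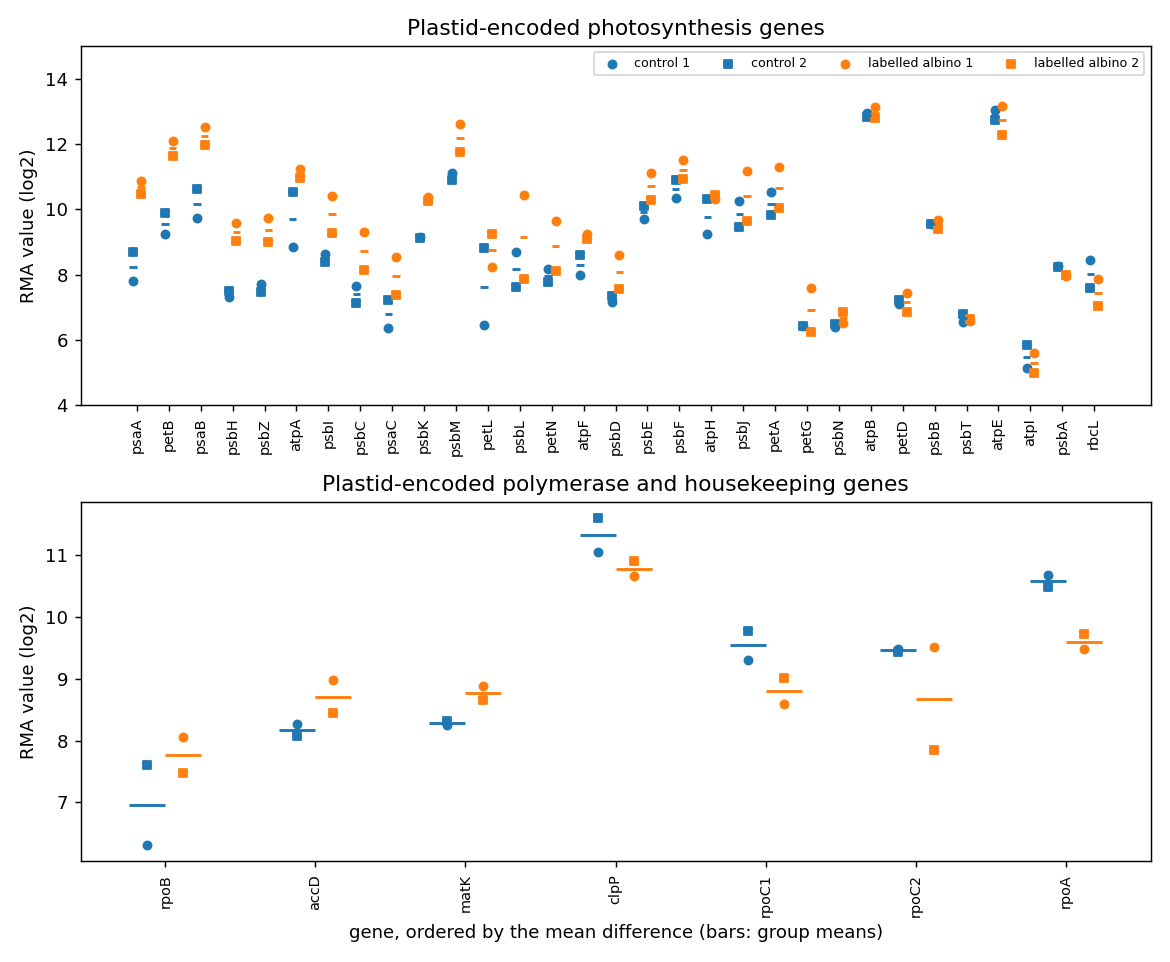
RMA values (log2) of each plastid-encoded photosynthesis gene (top) and polymerase or housekeeping gene (bottom) in the 4 arrays, with blue for labelled control, orange for labelled albino, circles for replicate 1, squares for replicate 2 and bars for group means. Genes run from the highest to the lowest mean difference, from 2.43 for psaA to -0.56 for rbcL in the upper panel.

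Genes for the plastid's own RNA polymerase and other housekeeping functions did not follow. The 7 measured of 9 had a median difference of -0.54 (0.04 in pair 1 and -0.69 in pair 2), and the list was not called (camera adjusted p = 0.569, block 0.609). The polymerase subunit gene rpoA was lower by a difference of -0.98 (SE 0.26), with -1.19 in pair 1 and -0.76 in pair 2. It had an adjusted p of 0.734 over all probe sets, and adjusted over the list alone 0.0749, or 0.0288 with the block. The subunit gene rpoC1 differed by -0.73 (SE 0.31), lower in both pairs. The pairs disagreed for rpoC2 (0.04 in pair 1 and -1.59 in pair 2) and rpoB (1.74 and -0.13). Higher in both pairs were accD of fatty acid synthesis, by 0.54 (SE 0.30), and the splicing factor gene matK, by 0.48 (SE 0.26). Among nuclear genes for plastid transcription 1 was measured, the phage-type polymerase RPOTMP, with a difference of 0.43 (SE 0.34). The 9 measured nuclear genes for plastid ribosomal proteins had a median difference of 0.00 (adjusted p = 0.976), and the one with the smallest p, PRPL19B, differed by -0.17 (SE 0.26).

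Nuclear photosynthesis genes had a median difference of 0.17 in pair 1 and 0.12 in pair 2 over the 12 measured. These were 2 of 18 listed genes of photosystem I and its antenna and 5 of 25 of photosystem II and its antenna. The others were 1 of 12 of electron transport and ATP synthase and 4 of 21 of the Calvin cycle. Of the 5 measured photosystem II and antenna genes, 4 were higher in both pairs and 1 was lower, with a median difference of 0.19 (0.27 in pair 1 and 0.10 in pair 2; camera adjusted p = 0.422, block 0.609). With a trended and robust prior the camera adjusted p was 0.0338, and with the block added to that prior it was 0.195. With an estimated correlation the adjusted p was 0.889. LHCB4.2, a minor antenna protein of photosystem II, went from 10.29 ± 0.03 to 11.64 ± 0.30 (SD, n = 2 each), 1.58 in pair 1 and 1.12 in pair 2. It was the 1 member to pass adjusted over the list alone, with 0 passing over all probe sets (adjusted p = 0.645, block 0.217). Its relatives LHCB4.1 and LHCB4.3 differed by 0.06 (SE 0.26) and -0.51 (SE 0.30). The photosystem I gene PSAN differed by 0.38 (SE 0.25) and the ATP synthase gene ATPC1 by 0.08 (SE 0.25). In the Calvin cycle list, with 4 measured and a median of 0.08 (adjusted p = 0.976), the phosphoglycerate kinase gene PGK2 differed by -0.62 (SE 0.31) and the Rubisco activase gene RCA by 0.21 (SE 0.25). The 4 photorespiration genes had a median of 0.09 (adjusted p = 0.976), with hydroxypyruvate reductase HPR1 at 0.29 (SE 0.26).

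None of the measured pigment synthesis genes passed the test, over all probe sets or adjusted over its list alone. The 8 measured genes of tetrapyrrole and chlorophyll synthesis had a median difference of -0.04 (adjusted p = 0.976), 3 being higher and 4 lower in both pairs. The geranylgeranyl reductase gene CHLP differed by 0.32 (SE 0.26) and the protochlorophyllide reductase gene PORB by 0.35 (SE 0.29). Of the carotenoid and plastid isoprenoid list 2 were measured, Z-ISO with a difference of -0.25 (SE 0.27) and LYCB with 0.26 (SE 0.30). The 4 measured flavonoid and anthocyanin genes had a median of 0.07 (adjusted p = 0.976), and the anthocyanin glucosyltransferase gene UGT75C1 differed by 0.21 (SE 0.29).

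Markers of oxidative stress and mitochondrial dysfunction, with 4 measured of 17 listed, fell in the arrays labelled albino as a list (median -0.78, camera adjusted p = 0.00376, block 0.0142). The adjusted p was 0.823 with an estimated correlation and 0.297 with fry, and leaving out albino replicate 1 or control replicate 2 gave 0.0685 and 0.305. The median was -0.72 in pair 1 and -0.50 in pair 2, with 3 members lower in both pairs. So was the root marker PYK10, but not the dim root markers EXPA7 and EXPA18. ZAT10, a zinc finger repressor induced by many stresses, went from 7.51 ± 0.07 to 6.61 ± 0.42 (SD, n = 2 each), with -0.55 in pair 1 and -1.24 in pair 2. Its limma adjusted p was 0.787 over all probe sets and 0.248 with the block. The gene recorded as AAA-ATPase (AT3G28580) differed by -0.80 (SE 0.25) at a dim signal, 4.24 and 3.44 in the group means, and leaving out the dimmest 25% of probe sets removed it and left the list too small to test. The alternative NADH dehydrogenase gene NDB2 differed by -0.75 (SE 0.51). None of the 4 passed over all probe sets or adjusted over the list alone, while 2 passed the latter with the block. The other stress lists had under 4 measured genes and no set test. The glucosyltransferase gene UGT73B5 differed by -0.79 (SE 0.36) and the small heat shock gene HSP17.6B, at a dim signal, by -0.45 (SE 0.25). The cold-responsive COR15A differed by 0.13 (SE 0.57).

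GI, which links the circadian clock to flowering, was the 1 measured gene of the light, greening and clock list. It went from 7.60 ± 0.25 to 9.65 ± 0.07 (SD, n = 2 each), with 2.17 in pair 1 and 1.92 in pair 2, at an adjusted p of 0.59 over all probe sets and 0.217 with the block. Of 2 measured jasmonate genes, THI2.1, a jasmonate-responsive antimicrobial thionin, went from 9.73 ± 0.78 to 11.88 ± 0.06 (SD, n = 2 each), with 2.74 in pair 1 and 1.55 in pair 2. Its limma adjusted p was 0.627 over all probe sets, 0.217 with the block, and 0.00474 adjusted over the list alone. The defensin gene PDF1.2A, at a dim signal, differed by -0.08 (SE 0.35).

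In primary metabolism, the 3 measured of 16 dark-inducible and carbon starvation genes were higher in both pairs, although MCCA by only 0.01 in pair 2. AKINBETA1, a subunit of the SnRK1 energy-sensing kinase, differed by 0.78 (SE 0.31, limma adjusted p = 0.856). The 4 starch genes had a median of 0.17 (adjusted p = 0.976), and DPE1, a plastid enzyme of starch breakdown, differed by 0.60 (SE 0.38). The sulfite reductase gene SIR differed by -0.60 (SE 0.28). BCAT4, which acts early in methionine-derived glucosinolate synthesis, differed by -0.77 (SE 0.26), lower in both pairs. The 4 cytosolic ribosomal protein genes had a median of -0.12 (adjusted p = 0.976), with RPL4D at -0.21 (SE 0.26). For the 9 tested lists without a call, block adjusted p lay between 0.609 and 0.892 and estimated-correlation adjusted p between 0.889 and 0.986.

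Markers of organs were few on the arrays as annotated here. PYK10, an abundant beta-glucosidase of roots and hypocotyls, went from 11.02 ± 0.23 to 9.54 ± 0.92 (SD, n = 2 each), with a limma adjusted p of 0.750 for the difference and 0.286 with the block. The root hair expansin genes EXPA7 and EXPA18 differed by -0.28 (SE 0.35) and 0.22 (SE 0.27). Both were dim, at 4.44 and 4.09 in the labelled control mean. CLV3, a peptide gene of the shoot meristem, differed by -0.20 (SE 0.54). The lists for plastid import, salicylate and senescence, cell cycle, flower and seed had 0 members measured and are not analysed here.

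The genes with the largest difference repeated in both pairs, chosen after their values were seen, lay mostly outside the lists. Higher in the arrays labelled albino were the expansin gene EXPA8 (3.09 in pair 1 and 2.38 in pair 2), the cytokinin-responsive regulator RR16 (3.48 and 2.25) and the lectin gene JAL23 (2.94 and 1.86). Lower were the sucrose transporter gene SAG29, also known as SWEET15 (-1.64 and -2.27), the plant defensin gene LCR67, also known as PDF1.1 (-2.40 and -1.56), and the genes AT1G43910 (-2.82 and -1.80) and AT4G12500 (-3.61 and -1.57). None passed limma's test over all probe sets in either fit.

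**Figure D3:**
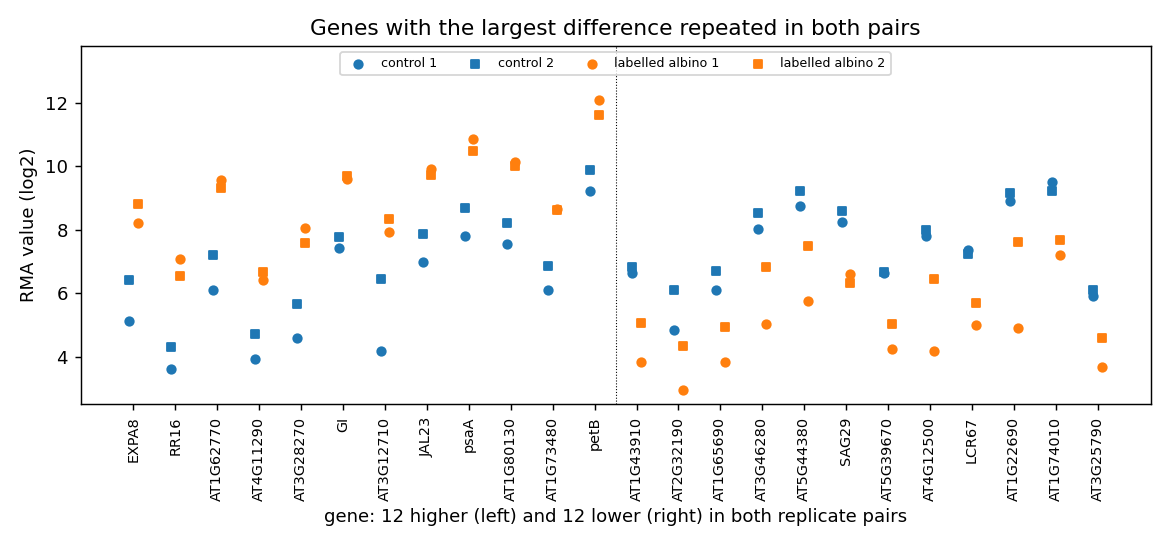
RMA values (log2) in the 4 arrays for the 12 genes with the largest positive and the 12 with the largest negative difference in both pairs, ranked by the smaller of the 2, with blue for labelled control, orange for labelled albino, circles for replicate 1 and squares for replicate 2. The difference of EXPA8 was 2.38 in pair 2, its smaller one.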

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

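The combined replicate block and estimated correlation, the block with a trended prior, the 2-fold criterion in both pairs and the gene classes were chosen after the data were seen. Counts of called probe sets were 0 in both directions under every alternative except 2. With no variance moderation 1 was called lower. Without albino replicate 2, 30 were called higher and 152 lower, the same counts at 2-fold or more, and 5 genes of the fixed lists were called, so over the 4 fits that leave out an array these counts ran from 0 to 30, 0 to 152 and 0 to 5. At unadjusted p under 0.05, limma gave between 663 and 3556 probe sets over these settings. The plastid-encoded photosynthesis list was past the threshold under each scaling, filter and left-out array, but not with an estimated correlation (adjusted p = 0.829), fry (0.523) or block and estimated correlation together (0.911). For the oxidative stress list the same 3 gave 0.823, 0.297 and 0.911, and the fits without 1 array ranged from 0.00251 to 0.305. Both filters on dim probe sets left it under 4 genes, with no value. The photosystem II list passed with a trended and robust prior (0.0338) and with fry (0.000115), but with the replicate block these were 0.195 and 0.0705. The root marker median moved from -0.28 to -1.48 with the dimmer 50% left out, which keeps PYK10 alone of the list, and ran from -0.71 to 0.15 without 1 array, and the CLV3 difference ran from -0.96 to 0.56 without 1 array. The causes of the other changes were not tested. No called result reversed. Of 114 genes followed under the alternatives 27 changed sign under at least 1. Any that passed the threshold did so with no variance moderation or without albino replicate 2, which leaves a single labelled albino array. Same-numbered arrays deviated together from their group means (r = 0.662 across genes, 0.558 after quantile normalization). With only 2 pairs this does not show that the numbers pair the samples. The replicate block gave 0 calls, and with the default prior and preset correlation no camera call of a fixed list changed with it.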

Other observations

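The tests described here were chosen after the results were seen, except that a test of chromosome position was planned on called genes. As 0 were called, it was run on genes that differed 2-fold in both pairs. Split by complex, the plastid genes for photosystem I had the highest median difference, although psaC (1.18) and psaI (1.36) lay below psbH of photosystem II (1.90). The median difference was 1.92 for the 5 psa genes (2.53 in pair 1 and 1.3 in pair 2), all higher in both pairs, and 0.83 for the 15 psb genes of photosystem II, 12 of them higher in both (1.43 in pair 1 and 0.23 in pair 2). It was 0.70 for the 6 pet genes (1.31 and 0.29), 0.40 for the 10 ndh genes of the NADH dehydrogenase-like complex (0.64 and -0.01) and 0.34 for the 6 atp genes (0.76 and 0.04), so that for ndh and atp it came from pair 1. The median was -0.75 for the 4 rpo genes of the plastid polymerase (-0.33 in pair 1 and -0.76 in pair 2). The ribosomal protein genes did not pass (camera adjusted p 0.0819 for 7 rpl and 0.151 for 8 rps genes), with medians of -0.46 and -0.36 that were -0.02 and -0.04 in pair 1. Pooled with rpo, the 19 gene expression genes had a median of -0.46 (-0.02 in pair 1 and -0.69 in pair 2; camera adjusted p 0.0056, block 0.00445), and all 69 plastid-encoded genes one of 0.49 (0.71 and 0.12; 1.75e-06, block 0.00136), 37 of them higher and 12 lower in both pairs. Ribosomal protein genes ranged widely, from rpl36 at -1.55 (SE 0.34) to rpl33 at 1.36 (SE 0.44). Camera adjusted p was 2.9e-10 for psa, 2.42e-08 for psb, 0.00196 for pet, 0.0108 for ndh, 0.0669 for atp and 0.0201 for rpo. With the block these were 7.58e-05, 2.26e-05, 0.00685, 0.0156, 0.171 and 0.0314. With an estimated correlation, a test with 2 residual degrees of freedom, no class passed (adjusted p between 0.365 and 0.512).

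Outside the plastid, 44 families of nuclear genes sharing a symbol stem were tested. The lowest adjusted p was that of the calmodulin-like CML genes, calcium-binding proteins, with a median of -0.32 over 7 genes, 5 of them lower in both pairs (camera adjusted p = 0.0646, block 0.019, estimated correlation 0.962). In the deposited values a larger structure ran along the replicate number and not the groups. Grouping the arrays by number gave 5218 probe sets at an unadjusted limma p under 0.05, against 1310 for the labelled groups and 13 for the crossed grouping, with 0 called in each. In both groups 524 probe sets differed at least 2-fold in the same direction between replicate 1 and 2. The deposited values look normalized as 2 separate pairs, which may add to these counts. No such count was made after normalizing all 4 arrays together. The dehydrin gene LTI30 read 10.65 and 10.10 in control and albino replicate 1 against 5.27 and 6.25 in replicate 2, and the late embryogenesis gene LEA4-5 read 8.29 and 7.69 against 4.50 and 3.98. The peptide gene CLE44 read 7.49 and 6.67 against 4.02 and 3.66. The cold-responsive gene COR47 did not follow, at 11.22 and 11.35 against 11.36 and 11.26.

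Higher plastid photosynthesis transcripts in arrays labelled albino are the first pattern. A larger share of plastid RNA as a whole would raise all plastid transcripts. Yet the photosynthesis classes exceeded the gene expression classes by 1.46 (SE 0.34) in pair 1 and 0.98 (SE 0.24) in pair 2. The gene expression classes had medians of -0.02 and -0.69, which argues against a larger plastid share as the whole source. These SEs are over genes within 1 pair of arrays, which are not independent replicates. The classes were chosen after the data were seen. A smaller share of root tissue, which would raise nuclear photosynthesis genes alike, stays open. The root marker PYK10 differed by -1.48, but EXPA18 was higher in both pairs (0.18 and 0.27) and EXPA7 went from -0.70 in pair 1 to 0.14 in pair 2. EXPA18 and EXPA7 are dim, where differences are compressed, so they weigh little against PYK10. The plastid list exceeded the nuclear genes by 1.09 (SE 0.31) in pair 1 but by only 0.11 (SE 0.21) in pair 2. Exchanged group labels stay open as a hypothesis, since the median of 12 nuclear photosynthesis genes was 0.17 in pair 1 and 0.12 in pair 2, neither clearly higher nor lower, and no targeted gene is known from the labels. The albino mutation itself, and the unstated priming of cDNA from plastid RNA, also remain open and were not tested.

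The smaller differences in pair 2 are the second pattern. A narrower value scale is argued against, since the ratio of the SDs of the pair differences (pair 1 over pair 2) was 1.65 as deposited and 1.76 after quantile normalization of all 4 arrays. A proportional weakening, which predicts 1 ratio of pair 2 to pair 1, stays open, because the ratio depended on how probe sets were grouped. From the smallest to the largest falls it moved by -0.20 (SE 0.027) grouped by the mean of both pairs, -0.10 (SE 0.025) by pair 1 and -0.05 (SE 0.136) by pair 2. From the smallest to the largest rises it moved by 0.02 (SE 0.034), 0.20 (SE 0.043) and 0.00 (SE 0.068). The SEs in this paragraph are over probe sets. RNA of normal plants mixed into albino replicate 2 may also limit the falls, but the share fitted at the largest falls was 33.5%, 36.5% or 14.4% by grouping, and rises of at least 1 lay -0.27 (SE 0.032), -0.46 (SE 0.02) and -0.18 (SE 0.057) from its prediction, so it stays open, as does an untested biological difference between the replicates.

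The plants were segregants, so alleles near the insertion or mutation could differ between the groups, and changed genes would then lie close together. Of the 13217 genes with a known order, 159 differed at least 2-fold in both pairs, and the densest window of 50 neighbouring genes held 5 of them, on chromosome 4 between AT4G29650 and AT4G30670. In 10000 shuffled orders the median was 4 and the 95th percentile 5 (permutation p = 0.291), so these genes neither show a linked block nor exclude one. By chromosome, the share of changed genes passed Fisher's exact test in none of 5 chromosomes in either direction (lowest adjusted p = 0.41).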
